A study of Mus musculus with 34 samples.

How the data were processed

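Epididymal fat of mice was compared on 34 two-colour arrays, each holding a Cy3-labelled RNA of 1 diet group and a Cy5-labelled RNA of another, per the labels. The deposited table gives 1 log ratio per probe and array for 25344 probes, with no missing value and no value of exactly 0. The values run from -6.31 to 7.99 and each array's median lies between -0.062 and 0.046, so the ratios the authors deposited are centred near 0 on every array. Background correction, normalization, spot filtering and the log base are not given in the sources used here. Base 2 was taken for the deposited log2 ratios, because a base of 10 would put the highest value beyond the 4.82 that 16-bit intensities allow; a natural log cannot be excluded, so no value was converted to a fold. The table holds no intensities, so no dim spots could be left out and the number of arrays limits the precision. RNA was extracted with Trizol in experiment 1 and with Qiagen reagents in experiment 2, per the labels.

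Which dye was the numerator of the ratio is not given in the sources used here. A rule fixed before the data were examined was to settle it from the fat mass expansion genes, whose mean should exceed that of the lipogenesis genes in HF0 against STD. The difference of the means was 0.06 in experiment 1 and 0.35 in experiment 2, but both lists had negative means themselves (-0.09 and -0.12 for expansion, -0.16 and -0.48 for lipogenesis), so the lists contradicted each other and no sign was read as more or less RNA. Every value is coded as Cy5 over Cy3, turned so that the first-named group stands over the second. Positive then means more RNA in the first-named group if Cy5 was the numerator, and less if Cy3 was; relative directions hold on either reading.

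Probes were named through the platform annotation of the probes: 21082 had 1 gene symbol, 30 had several and 4232 had none, and 20456 symbols were updated through the gene ID to the reference gene table. Probes of 1 gene were averaged (1668 genes had more than 1 probe; Actb had 305 and Gapdh 257), probes with several symbols or none stayed separate, and 22879 features were tested, 18617 of them with a symbol. As a check of the naming, 23 genes with exactly 2 variable probes had a median correlation of 0.85 between their probes over the arrays, against -0.02 for random probe pairs.

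Each array was centred on its median. The sign-turned arrays of a dye swap were averaged, because nothing says that they hold different RNA. Group values were estimated by least squares within each experiment, relative to the mean of its STD, HF0, HF3 and HF4. Where HF0, HF3 or HF4 is compared with HF1 or a reversal group, it enters as its average over both experiments. STD acts on those comparisons through the mean. The 12 group values (4 groups of experiment 1 and 8 of experiment 2) were then tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the experiment as a block, 3 residual and 3.16 prior degrees of freedom, and Benjamini-Hochberg adjustment over all features; the threshold was an adjusted p of 0.05. STD, HF0, HF3 and HF4 thus have n = 2 experiments, while HF1 and the reversal groups have n = 1 and were assumed to vary like the others. The labels do not say how many animals stand behind an extract, so the p-values measure only the spread between extracts of the experiments, which may be technical. Preparation and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

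On simulated data with known answers over 22879 features, the comparison of HF4 with HF0 recovered 2 of 100 features changed by 1 log2 unit and 72 of 100 changed by 2, with 3 calls among unchanged features. For HF4 against STD it recovered 4 and 76 of 100, with 1 such call. Small changes are therefore mostly beyond this design. Changes were put into HF4 alone, so the 0 calls in HF1 against HF0 are a check of false calls only. Recovery was not simulated for the groups with n = 1.

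The 15 gene lists and 9 lists of cell type markers, fixed before the data were examined, were tested with camera (preset correlation 0.01) in 11 comparisons, with camera at an estimated correlation and with fry as alternatives. In all, 73 of 264 list tests passed with the preset correlation and 0 passed with the estimated correlation or with the directional test of fry, where the lowest adjusted p was 0.282 and 0.0506. Without regard to direction, 45 passed with fry. After the results had been seen, list medians were also taken within each experiment, and named genes were correlated with the mean of the male germ cell list over the 12 group values (Pearson's r). Genes were named by a rule fixed beforehand: the 8 most positive and 8 most negative genes past the threshold whose arrays holding both groups all had the same sign (the 5 most extreme at an unadjusted p under 0.05, as values only, where fewer than 5 genes passed), up to 4 members of each list past the threshold, up to 3 of each list past the camera threshold as values, and Lep, Mest, Adipoq, Scd1, Fasn, Ucp1, Tnf, Ccl2 and Adgre1 in HF0 and HF4 against STD. The condition on arrays was not applied to the slope over generations, the mean over the reversal comparisons and the differences of diet effects. Lists of male germ cell, Leydig and Sertoli cell and epididymis genes were written after first results had been seen, as were the enrichment tests of gene families (one-sided Fisher's exact test over the 18617 genes with a symbol).

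The alternatives were no centring, scale and quantile normalization, only features measured on all arrays, each probe on its own (25344 tests), the spread of arrays within experiments as the error, all arrays as replicates with a dye effect, each experiment alone, only arrays holding both groups, leaving out the last hybridisation day, a robust variance prior, leaving out each array and turning all signs. After the data had been seen, the features that correlated above 0.8 in absolute value with the mean of the male germ cell list, and separately the STD extract of experiment 2, were also left out.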

Results

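Gene expression was measured in the epididymal fat of mice kept on a normal diet (STD) or on a high fat diet over successive generations. HF0 mice were the high-fat offspring of STD mice, and HF1 the offspring of HF0. HF3 descended from an HF2 generation that has no arrays here, and HF4 from HF3. HF1-REV, HF3-REV and HF4-REV mice had the same parents as their namesakes but ate the normal diet. Experiment 1 held 12 arrays with all pairings of STD, HF0, HF3 and HF4. Experiment 2 held 22 arrays with all pairings of HF0, HF1, HF3 and HF4, HF0 against STD on 4 arrays, and each high fat group against its reversal group on 2. Each pairing was hybridised in both dye orientations. Values are log2 ratios ± SE of the first-named group over the second, coded as Cy5 over Cy3. The numerator of the deposited ratios is not known, so positive and negative give relative directions only. If Cy5 was the numerator, positive means more RNA in the first-named group, and if Cy3 was, every sign turns.

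Epididymal fat lies against the epididymis and testis, and transcripts of both organs separated the extracts. Over 31 male germ cell genes, a list written after first results had been seen, the median against HF0 was 1.53 in HF3 and 2.66 in HF4 of experiment 1, and 2.01 and 3.31 in experiment 2. It was 0.55 and 1.70 in STD, 0.08 in HF1, and -0.27, 0.13 and -0.01 in HF1-REV, HF3-REV and HF4-REV. Over 23 genes of the epididymis epithelium, STD stood at 1.23 against HF0 in experiment 1 and at 4.46 in experiment 2, where the other groups lay between -0.26 and 0.63.

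**Figure D1:**
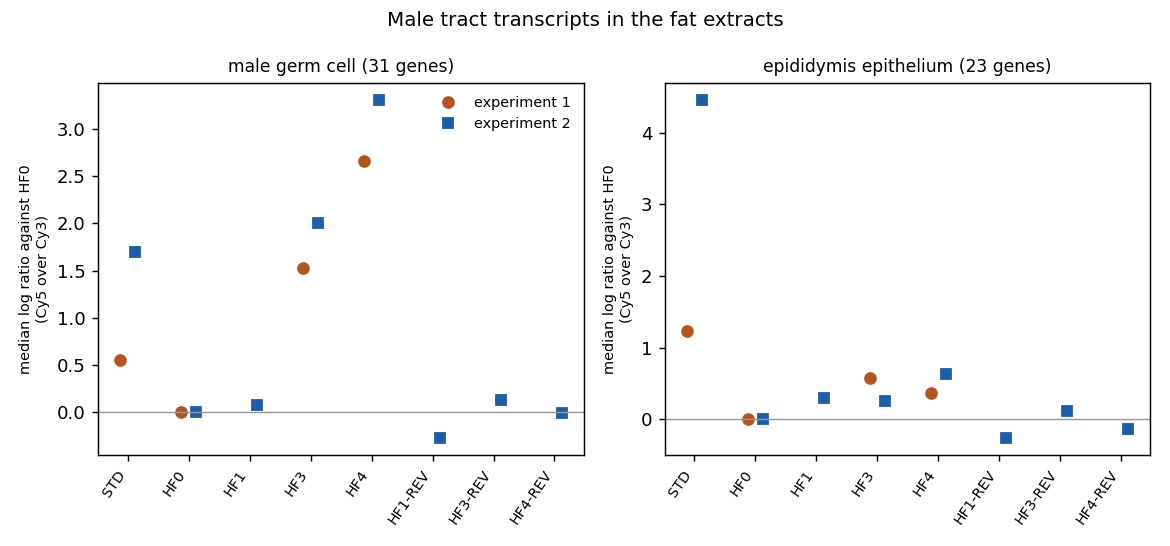
Median log2 ratio against HF0 (coded Cy5 over Cy3) of 31 male germ cell genes and 23 epididymis epithelium genes for each diet group; circles are experiment 1, squares experiment 2, each from 1 set of group values, and HF0 is 0 by definition. The germ cell median reaches 2.66 and 3.31 in HF4, and the epididymis median reaches 4.46 in STD of experiment 2.

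The first question is what a high fat diet did to fat in the first generation. In HF0 against STD, genes of the mature adipocyte lay together on the negative side and genes of macrophages on the positive side. Of 20 measured genes of lipid storage and adipocyte identity, 18 were negative (median -0.54). Among them were Retn, which encodes the adipokine resistin (-1.34 ± 0.12), Cidec, a lipid droplet protein (-1.29 ± 0.23), and Adipoq, which encodes adiponectin (-1.24 ± 0.26, n = 2 for each). The list passed with camera (adjusted p = 3.68e-09), but not with an estimated correlation (adjusted p = 0.446). All 23 macrophage markers were positive (median 0.57, adjusted p = 1.63e-11, but adjusted p = 0.446 with an estimated correlation). They were led by Mmp12, the macrophage elastase (2.18 ± 0.46), and Lgals3, which encodes galectin-3 (1.26 ± 0.33). Lipogenic genes were negative for 16 of 21 (median -0.17, adjusted p = 0.00283), with Thrsp at -1.28 ± 0.19 and the desaturase genes Scd1 and Scd2 at -1.12 ± 0.35 and -0.96 ± 0.40. Endothelial markers had a median of -0.49 (adjusted p = 9.82e-05), with Kdr, a VEGF receptor, at -1.04 ± 0.36. Lipogenic and endothelial lists each had adjusted p = 0.446 with an estimated correlation.

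Extracellular matrix genes were positive for 24 of 29 in HF0 against STD (median 0.23, adjusted p = 9.82e-05), and inflammatory mediators for 17 of 24 (median 0.31, adjusted p = 0.00186). Prostanoid and leukotriene genes had a median of 0.23 (adjusted p = 0.00282) and B cell markers one of 0.40 (adjusted p = 0.00283). All 4 lists had adjusted p = 0.446 with an estimated correlation. Oxidative phosphorylation had a median of -0.17 (adjusted p = 0.00307, but adjusted p = 0.5 with an estimated correlation), which was 0.07 in experiment 1 and -0.40 in experiment 2, so its sign turns. Within the inflammatory list Ptgs2, the inducible cyclooxygenase, lay at 1.04 ± 0.42, and the acute phase genes Lcn2 and Orm1 at -2.32 ± 0.76 and -1.03 ± 0.38. Of the prostanoid list, Ptgds stood at -1.62 ± 0.53. In STD against HF0 the highest inflammatory and prostanoid members stood at 0.69 and 0.44 in experiment 1, and at 3.95 and 2.79 in experiment 2. Large negative values of these lists thus rest mainly on the STD extract of experiment 2, which stands apart in epididymis transcripts. They are not read as a diet effect in fat. The leptin gene Lep stood at -0.23 ± 0.12, Mest at -0.36 ± 0.20, Fasn at 0.13 ± 0.15 and Ucp1 at 0.24 ± 0.19. Tnf stood at 0.48 ± 0.23, Ccl2 at 0.49 ± 0.26 and Adgre1 at 0.50 ± 0.15. The most extreme values belonged to epididymis genes: Cst11 at -4.49 ± 1.16, Defb20 at -4.18 ± 0.83 and Spink12 at -4.12 ± 1.07 (all 6 arrays negative). The epididymis, testis and seminal vesicle markers had a median of -2.82 (adjusted p = 1.67e-08, but adjusted p = 0.446 with an estimated correlation).

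In HF0 against STD, 0 genes passed limma's test, and the robust prior gave 0 as well; 1685 had an unadjusted p under 0.05. Of the lists past the camera threshold, adjusted over the list alone, 5 adipocyte genes, 5 macrophage markers, 1 lipogenic gene and 11 of the 16 male tract markers passed, against 0 over all genes. The experiments differed in the size of most list medians: it was 0.17 and 0.99 for macrophage markers, -0.09 and -0.80 for endothelial markers, 0.04 and 0.52 for prostanoid genes and 0.05 and 0.53 for inflammatory mediators, but -0.49 and -0.62 for adipocyte genes. Among genes, Mmp12 was 1.21 in experiment 1 and 3.16 in experiment 2, Cst11 -2.39 and -6.60, whereas Retn was -1.22 and -1.46 and Adipoq -1.09 and -1.39. Across the features, which are not independent replicates, the effects of the experiments correlated with r = 0.33.

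**Figure D2:**
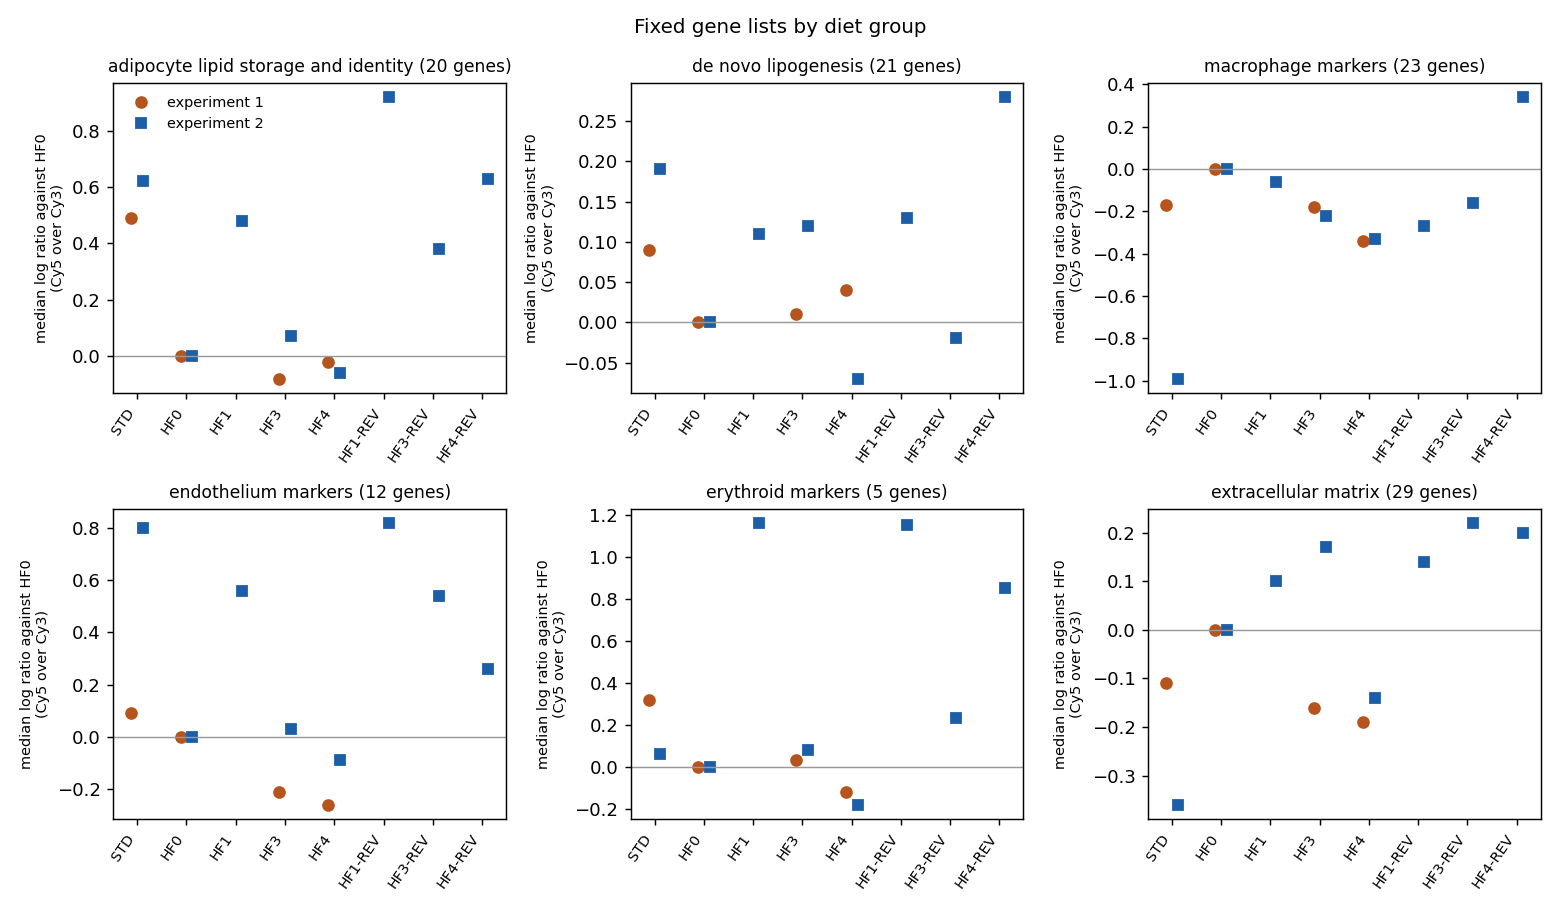
Median log2 ratio against HF0 (coded Cy5 over Cy3) of 6 fixed gene lists for each diet group; circles are experiment 1, squares experiment 2, and the vertical scales differ between panels. The adipocyte list lies at 0.49 and 0.62 in STD, between -0.08 and 0.07 in HF3 and HF4, at 0.48 in HF1, and at 0.92, 0.38 and 0.63 in HF1-REV, HF3-REV and HF4-REV.

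HF4 against STD asks how far the last high fat generation stood from the normal diet. Both this comparison and HF0 against STD rest on the same 2 STD extracts, so a shift of STD alone would enter both. The adipocyte list lay on the negative side for 16 of 20 genes (median -0.51, adjusted p = 3.64e-06, but adjusted p = 0.375 with an estimated correlation). Retn passed the gene test at -1.12 ± 0.12 (adjusted p = 0.0402, n = 2), while Cidec at -1.49 ± 0.23 and Adipoq at -1.18 ± 0.26 did not. In HF4 against HF0 the list had a median of 0.02, with 10 of 20 genes positive. The other genes that passed on the negative side were Cyp2e1, a cytochrome P450 (-1.77 ± 0.19, adjusted p = 0.0402), and Mylk, the myosin light chain kinase (-1.37 ± 0.16, adjusted p = 0.0464). On the positive side the 97 that passed were led by genes of the male germ line. They included Crisp2 (2.61 ± 0.19, adjusted p = 0.0334), the sperm acrosome gene Spaca1 (2.59 ± 0.25) and the sperm phospholipase gene Plcz1 (2.35 ± 0.27). Of the 31 germ cell genes 5 passed (adjusted p = 7.66e-06, Fisher's exact test). That list was written after first results had been seen, so its p-value is no separate support. All 12 endothelial markers were negative (median -0.65, adjusted p = 8.14e-06, but adjusted p = 0.577 with an estimated correlation), with Kdr at -1.24 ± 0.36.

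Fatty acid oxidation genes were negative for 19 of 20 in HF4 against STD (median -0.22, adjusted p = 0.000256, but adjusted p = 0.375 with an estimated correlation). The exception was Cpt1b at 0.74 ± 0.19. Oxidative phosphorylation had a median of -0.27 and cholesterol synthesis one of -0.26 (adjusted p = 0.0013 and 0.0242, but adjusted p = 0.747 with an estimated correlation for each). Their medians were -0.03 and -0.02 in experiment 1, and -0.51 and -0.30 in experiment 2. Immediate early and heat shock genes had -0.24, with Btg2 at -1.18 ± 0.24, and lipogenesis had -0.19 (adjusted p = 0.0226 and 0.00866, but adjusted p = 0.588 with an estimated correlation for each). All 5 erythroid markers were negative (median -0.20, adjusted p = 0.0422, but adjusted p = 0.577 with an estimated correlation). Inflammatory mediators were positive for 16 of 24 (median 0.26, adjusted p = 0.0402, but adjusted p = 0.747 with an estimated correlation), with Il6 at 2.04 ± 0.68 and Ptgs2 at 1.84 ± 0.42. Macrophage markers were positive for 19 of 23 (median 0.17, adjusted p = 0.0196, but adjusted p = 0.75 with an estimated correlation), with Mmp12 at 1.78 ± 0.46. Their median was -0.11 in experiment 1 and 0.62 in experiment 2, so the sign turns. Lep stood at -0.09 ± 0.12, a sign that turned to 0.04 under scale normalization. Mest stood at -0.49 ± 0.20, Scd1 at -1.10 ± 0.35, Fasn at -0.07 ± 0.15 and Ucp1 at 0.32 ± 0.19. The inflammatory genes Tnf and Ccl2 had 0.48 ± 0.23 and 0.56 ± 0.26, and Adgre1 had 0.01 ± 0.15. The signs of Fasn, Ucp1 and Adgre1 turned in experiment 1 alone (0.01, -0.07 and -0.11).

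In HF4 against STD, 100 genes passed, all with the same sign in both experiments, against 59.8% of all features. The error of the test is the spread between experiments, so a call nearly requires the same sign and this is no separate support. Of the lists past the camera threshold, 8 adipocyte genes, 4 endothelial markers and 1 early response, 1 inflammatory and 1 erythroid gene passed adjusted over the list alone, against 1 adipocyte gene over all genes. Of the 100 calls 88 correlated above 0.8 in absolute value with the germ cell list, which itself differs in HF4. Quantile normalization left 0 by limma (3290 at an unadjusted p under 0.05). Without the STD extract of experiment 2, 898 passed. Leaving out 1 array moved the count to between 45, without HF3 with HF0, experiment 2 replicate 2, and 147, without HF0 with STD, experiment 2 replicate 4.

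The next comparisons follow the high fat line from one generation to another. In HF1 against HF0, where HF1 was measured in experiment 2 alone, adipocyte, blood vessel and red cell genes lay on the positive side. The adipocyte list had 18 of 20 members positive (median 0.40, adjusted p = 1.16e-07), with the fatty acid transporter gene Cd36 at 2.45 ± 0.75 and Retn at 1.56 ± 0.15. All 5 erythroid markers were positive (median 1.15, adjusted p = 1.78e-06). Of these Alas2, the first enzyme of heme synthesis in red cell precursors, had 1.56 ± 0.20, and the globin genes Hbb-b1 and Hba-a1 had 1.28 ± 0.28 and 1.15 ± 0.21. The adipocyte and erythroid lists had adjusted p = 0.282 with an estimated correlation. Endothelial markers had a median of 0.37 (Kdr 1.78 ± 0.46, list adjusted p = 0.00196). Lipogenesis had one of 0.14 (Thrsp 1.95 ± 0.24, Acly 1.34 ± 0.28, list adjusted p = 0.0327), and B cell markers one of -0.44 (adjusted p = 0.0139). These last 3 lists had adjusted p = 0.661 with an estimated correlation. Other extreme values were those of Lcn5, an epididymal lipocalin (2.76 ± 0.78), and Bst2 (2.00 ± 0.54). On the negative side were S100a8, a neutrophil calcium-binding protein (-1.28 ± 0.33), and Selp, which encodes P-selectin (-1.36 ± 0.36).

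In HF1 against HF0, 0 genes passed limma's test, with the standard or the robust prior, and 1643 had an unadjusted p under 0.05. Of the lists past the camera threshold, 3 adipocyte genes, 3 erythroid markers, 3 endothelial markers and 2 lipogenic genes passed on the positive side and 2 B cell markers on the negative side adjusted over the list alone, against 0 over all genes. In lists that did not pass, so did 2 fat mass expansion markers on the positive side, and 1 hypoxia, 1 early response and 1 mast cell gene on the negative side. HF1 is a single set of extracts, so these values have no second experiment beside them. HF0 enters as its average over both experiments, so they are not differences within experiment 2 alone. Within experiment 2, Retn stood at 1.61 and Thrsp at 2.1 in HF1 against HF0.

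In HF3 against HF0 the most positive values belonged to Tnp1, a transition protein of sperm chromatin (3.45 ± 0.86), Clec2m (3.26 ± 0.37), Mael, a germ cell gene of transposon control (3.18 ± 0.58), the protamine gene Prm1 (3.11 ± 0.75) and Crisp2 (3.04 ± 0.19). On the other side were the calgranulin genes S100a9 at -1.36 ± 0.30 and S100a8 at -1.35 ± 0.26, and Camp, the cathelicidin, at -0.90 ± 0.19 (all 4 arrays negative for each). Hypoxia response genes were positive for 11 of 13 (median 0.29, adjusted p = 0.00526, but adjusted p = 0.788 with an estimated correlation), with Hk2, hexokinase 2, at 0.77 ± 0.13. That list had 0.01 in experiment 1 and 0.61 in experiment 2. Macrophage markers were negative for 17 of 23 (median -0.23, adjusted p = 0.0305, but adjusted p = 0.988 with an estimated correlation), with Adgre1 at -0.63 ± 0.15. The male tract markers had a median of 0.31 (adjusted p = 0.000515, but adjusted p = 0.788 with an estimated correlation). Here 0 genes passed limma's test (0 with the robust prior, 1785 at an unadjusted p under 0.05). Of these 3 lists, 6 male tract markers and 1 hypoxia gene passed adjusted over the list alone, against 0 over all genes. Scale normalization gave 141 calls, and leaving out the STD extract of experiment 2 gave 584.

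In HF4 against HF0, 963 genes passed, 959 of them positive, and male germ cell genes were enriched among them. Clec2m stood at 5.16 ± 0.37 (adjusted p = 0.00554), Pdcl2 at 4.86 ± 0.34 (adjusted p = 0.00554) and the meiosis gene Meig1 at 4.66 ± 0.51 (adjusted p = 0.00986). Crisp2 had 4.65 ± 0.19 (adjusted p = 0.00486), Ropn1l, a sperm tail protein gene, 4.63 ± 0.52, Spz1 4.63 ± 0.45 and Mael 4.60 ± 0.58 (n = 2, all 4 arrays positive for each). The sperm chromatin genes Tnp1, Tnp2, Prm1 and Prm2 also passed, at 4.56 ± 0.86, 4.50 ± 0.88, 4.45 ± 0.75 and 3.37 ± 0.43. The germ cell list and the families below were chosen after first results had been seen, and Fisher's test takes genes as independent. Its p-values therefore describe the calls and are no separate support. Of the 31 male germ cell genes 25 were among the 847 positive genes with a symbol (adjusted p = 4.52e-27, Fisher's exact test). So were 13 of 32 Tex, 11 of 24 Spata and 8 of 21 Cfap genes (adjusted p = 1.02e-08, 3.13e-08 and 2.13e-05), families named for testis, spermatogenesis and the cilium. Of the other families tested, Odf, Ccdc, Adam, Tssk, Spaca and Catsper passed, while Spag (2 of 9, adjusted p = 0.201), Tekt (1 of 5, adjusted p = 0.64) and Dnah (1 of 13, adjusted p = 1) did not. Pdpk1, a kinase of insulin signalling, was positive too (1.70 ± 0.25, adjusted p = 0.02), but it correlated with the germ cell list at r = 0.96 over the 12 group values. Of the 963 calls 875 moved with that list (r above 0.8 in absolute value). The list itself differs in HF4, so this does not tell where a transcript comes from. On the negative side Scamp5 (-0.64 ± 0.12, adjusted p = 0.043) and Rgl1 (-0.61 ± 0.12, adjusted p = 0.0423) passed.

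Extracellular matrix genes were negative in HF4 against HF0 for 28 of 29 members (median -0.21), with Col5a3 at -0.57 ± 0.14. Macrophage markers were negative for 22 of 23 (median -0.36), with Laptm5 at -0.52 ± 0.22 and Cd68 at -0.50 ± 0.28. Both lists, and the male tract markers at a median of 0.26, had an adjusted p of 0.00287 with camera and adjusted p = 0.942 with an estimated correlation. Over all genes 4 male tract markers passed and 0 matrix or macrophage genes, and adjusted over the list alone it was 5 and 0. The effects of the experiments correlated with r = 0.83 across the features (0.43 by rank), and 63.4% of the features had the same sign in both. All 963 called genes did, which a test with the spread between experiments as its error nearly fixes. Experiment 1 alone and the arrays holding both groups alone gave 0 each by limma (2699 and 2105 at an unadjusted p under 0.05).

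In HF4 against HF3 the most positive values included those of Pdcl2 (1.94 ± 0.34), Clec2m (1.90 ± 0.37) and the sperm histone genes H1f7 (1.95 ± 0.69) and H2bl1 (1.93 ± 0.43). Matrix, hypoxia, early response and inflammatory genes lay on the negative side. Extracellular matrix genes had a median of -0.27 (adjusted p = 0.00019), with the collagen gene Col1a1 at -0.92 ± 0.43. Hypoxia response genes had one of -0.31 (adjusted p = 0.00073), with Adm, adrenomedullin, at -0.85 ± 0.35. In experiment 1 the medians of these lists were -0.07 and -0.03, and in experiment 2 -0.46 and -0.48. Immediate early and heat shock genes had a median of -0.34 (adjusted p = 0.000155), with Zfp36 at -0.62 ± 0.22 and Fos at -0.55 ± 0.18, and inflammatory mediators one of -0.24 (adjusted p = 0.0213), with Il6 at -0.73 ± 0.68. Endothelial and erythroid markers had -0.13 and -0.25 (adjusted p = 0.0339 and 0.0485). All of these lists had adjusted p = 0.867 with an estimated correlation, and none of their members passed over all genes or adjusted over the list alone. In all, 0 genes passed limma's test (0 with the robust prior, 1259 at an unadjusted p under 0.05).

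The slope over HF0, HF1, HF3 and HF4, in log2 units per generation, rests partly on the same group values as HF4 against HF0, so the germ line genes on its positive side are no second finding. Of 1158 genes past the threshold 1143 were positive. Clec2m had 1.43 ± 0.09 and Pdcl2 1.34 ± 0.08 (adjusted p = 0.00261 for both), Tnp1 1.32 ± 0.20, Meig1 1.32 ± 0.12 and Prm2 0.92 ± 0.10. Also positive were Hk2 (0.27 ± 0.03, adjusted p = 0.00698), Cpt1b, the muscle form of carnitine palmitoyltransferase (0.27 ± 0.05, adjusted p = 0.0256), Fabp3, a fatty acid binding protein (0.27 ± 0.04), and Pdpk1 (0.43 ± 0.06). Hdc, which makes histamine, had 0.16 ± 0.03. Among the 15 negative genes were Alas2 (-0.24 ± 0.04, adjusted p = 0.0197) and G0s2, an inhibitor of lipolysis (-0.21 ± 0.03, adjusted p = 0.0197). Stab1, a scavenger receptor, had -0.18 ± 0.04 and Dnase1l3 had -0.14 ± 0.03. Over the 12 group values Pdpk1, Fabp3, Cpt1b, Hk2 and Hdc correlated with the germ cell list at r = 0.96, 0.87, 0.82, 0.79 and 0.72, and Stab1, G0s2, Dnase1l3 and Alas2 at -0.89, -0.72, -0.70 and -0.69. The list itself differs along the generations, so a called slope and a high r go together and do not tell where a transcript comes from.

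Several lists had small negative slopes, past the threshold with camera but not with an estimated correlation (adjusted p = 0.714 for each). Macrophage and erythroid markers had -0.10 each (adjusted p = 0.00127 and 0.00491), endothelial markers -0.09 (adjusted p = 0.00707), and extracellular matrix -0.06 (adjusted p = 0.00394). Adipocyte and fatty acid oxidation genes also had -0.06 (adjusted p = 0.0147 for both). The male tract markers had 0.12 (adjusted p = 0.00127), with 5 of 16 past the threshold over all genes and adjusted over the list alone. Each of these lists had adjusted p = 0.714 with an estimated correlation. In experiment 2, HF1, HF3 and HF4 had medians against HF0 of 1.16, 0.08 and -0.18 for erythroid markers. They were 0.56, 0.03 and -0.09 for endothelial markers and 0.48, 0.07 and -0.06 for adipocyte genes. These lists lay furthest from HF0 in HF1, a single set of extracts, so their slopes are no steady course over generations. Alas2, an erythroid marker, was also positive in HF1 against HF0.

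The reversal groups ask whether the normal diet changed fat in mice with high fat parents. In HF1 against HF1-REV, adipocyte genes lay on the negative side for 18 of 20 (median -0.36, adjusted p = 4.05e-06, but adjusted p = 0.758 with an estimated correlation). The 2 arrays behind these values hardly repeat each other. Their correlation was 0.34 over the probes, where a dye swap should make it negative, and -0.08 after the dye effect was removed, the nearest to 0 of all dye swaps. Pck1, a carboxykinase that makes glycerol for lipid storage, had -1.15 ± 0.32 and Cidec -1.11 ± 0.32. Cholesterol synthesis genes were positive for 18 of 20 (median 0.25, adjusted p = 0.000338, but adjusted p = 0.831 with an estimated correlation), with Msmo1 at 0.77 ± 0.46 and Hmgcs1 at 0.63 ± 0.29. All 10 T cell markers were negative (median -0.49, adjusted p = 0.000679, but adjusted p = 0.921 with an estimated correlation). All 12 endothelial markers were negative too (median -0.34, adjusted p = 0.000693), and fatty acid oxidation had a median of -0.23 (adjusted p = 0.0266), each with adjusted p = 0.831 with an estimated correlation. Macrophage markers had 0.21 and prostanoid genes 0.19 (adjusted p = 0.00954 and 0.0266, but adjusted p = 0.921 with an estimated correlation for both).

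The most positive values in HF1 against HF1-REV were male tract genes, Spink8 at 4.48 ± 0.85, Prm2 at 4.37 ± 0.61 and Lcn5 at 4.26 ± 0.87, positive on both of 2 arrays. Their list had a median of 0.32 (adjusted p = 0.000651, but adjusted p = 0.831 with an estimated correlation), and 2 members passed adjusted over the list alone. Here 0 genes passed limma's test over all genes (0 with the robust prior, 821 at an unadjusted p under 0.05). Where 1 array of a reversal pair is left out, here and below, the dye effect of the array kept no longer cancels and enters the count. Leaving out HF1 with HF1-REV, replicate 1 or replicate 2, gave 166 or 281.

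In HF3 against HF3-REV the adipocyte list was negative as well for 17 of 20 (median -0.45, adjusted p = 0.000927), with Pck1 at -0.92 ± 0.28 and the adipogenic receptor gene Pparg at -0.80 ± 0.32. Fatty acid oxidation genes were negative for 19 of 20 (median -0.23, adjusted p = 0.00409). Adipocyte and oxidation lists had adjusted p = 0.689 with an estimated correlation. Endothelial markers had a median of -0.50 (adjusted p = 0.00409), with Sox18, a vascular transcription factor, at -1.01 ± 0.21. Male tract markers had one of 0.88 (adjusted p = 0.00409). In experiment 2 itself the male tract markers had medians against HF0 of 0.43 in HF3 and 0.09 in HF3-REV. HF3 enters as its average over both experiments, relative to groups that include STD. The 0.88 thus also holds the STD extract of experiment 2, which is in neither group. Inflammatory mediators were positive for 18 of 24 (median 0.32, adjusted p = 0.045), with the interleukin gene Il1b at 2.03 ± 0.37 and its antagonist Il1rn at 1.19 ± 0.18. The last 3 lists had adjusted p = 0.719 with an estimated correlation, and 2 inflammatory genes, 2 endothelial markers and 1 adipocyte gene passed adjusted over the list alone, against 0 over all genes.

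Among the 20 genes past the threshold in HF3 against HF3-REV, 12 positive and 8 negative, was the meiotic gene Sycp3 (1.95 ± 0.17). Crisp2 (3.14 ± 0.25), Dmc1 (1.43 ± 0.14), Olfr995 (-2.23 ± 0.17) and Usp29 (-1.81 ± 0.14) also passed, each of the 5 with an adjusted p of 0.0458. The arrays disagreed in size for several, as for Slx4 (1.84 ± 0.16), which stood at 0.28 and 3.51 on them. Dmc1 and Slx4 differed in HF3-REV, at -1.39 and -1.87 against HF0, and lay between -0.18 and 0.12 in the other groups. The sides depend on the scaling, with 188 positive and 60 negative under scale normalization and 87 positive and 123 negative under quantile normalization. The correlation of the 2 arrays was -0.22 after the dye effect was removed. The count was 0 by limma without the last hybridisation day or with each probe on its own (2867 and 3756 at an unadjusted p under 0.05). It moved by more than 1.5 times for 23 of the 34 arrays left out, to 1702 or 2300 without HF3 with HF3-REV, replicate 1 or replicate 2.

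HF4 against HF4-REV gave 2552 calls, of which 1682 were positive and 870 negative. It was 927 and 204 under scale normalization, and 83 and 53 under quantile normalization, fewer than in HF3 against HF3-REV there. Germ line genes led the positive side, with Crisp2 at 5.88 ± 0.25 (adjusted p = 0.00612), Clec2m at 5.74 ± 0.47, Spz1 at 5.68 ± 0.57, Pdcl2 at 5.57 ± 0.43 and the sperm surface gene Adam3 at 5.43 ± 0.66. Of the 31 germ cell genes 26 passed (adjusted p = 1.26e-23, Fisher's exact test), a list written after first results had been seen, so this p-value is no separate support. Among the most negative genes Alas2 had -2.84 ± 0.20 (adjusted p = 0.00931) and Fech, the last enzyme of heme synthesis, -2.80 ± 0.25 (adjusted p = 0.0114). The lysozyme gene Lyz1 had -2.83 ± 0.66, Retnlg, a neutrophil resistin-like gene, -2.60 ± 0.46, and Folr2, a marker of resident macrophages, -2.57 ± 0.61. Macrophage markers were negative for 20 of 23 (median -0.59, adjusted p = 0.000323, but adjusted p = 0.786 with an estimated correlation). Of these C1qb (-1.55 ± 0.34), Tyrobp (-1.29 ± 0.28) and Adgre1 (-1.04 ± 0.19) passed. All 5 erythroid markers were negative (median -0.87, adjusted p = 0.00416, but adjusted p = 0.469 with an estimated correlation).

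Adipocyte genes were negative for 20 of 20 in HF4 against HF4-REV (median -0.57, adjusted p = 3.6e-05, but adjusted p = 0.469 with an estimated correlation), with Retn past the threshold at -1.49 ± 0.15 (adjusted p = 0.0124). Respiratory chain genes had a median of -0.19 (adjusted p = 0.00605, but adjusted p = 0.786 with an estimated correlation). Of these 6 of 25 passed on the negative side, among them Ndufs3 (-1.52 ± 0.33) and Sdhb (-1.29 ± 0.27). Fatty acid oxidation had -0.33 (adjusted p = 0.011, but adjusted p = 0.541 with an estimated correlation). T cell markers had -0.66 (adjusted p = 0.0221, but adjusted p = 0.828 with an estimated correlation). Extracellular matrix had -0.30 and prostanoid genes -0.53 (adjusted p = 0.00878 and 0.011, but adjusted p = 0.786 with an estimated correlation for both). Of the prostanoid list Hpgds, Ltc4s and Alox5 passed at -0.93 ± 0.17, -1.14 ± 0.27 and -0.95 ± 0.21, and Ptgs2 at 2.36 ± 0.53. Other genes past the threshold on the negative side were the lipogenic Thrsp (-1.43 ± 0.24), Npr3 (-0.76 ± 0.17), the chemokine genes Ccl8 and Ccl3 (-1.46 ± 0.31 and -1.05 ± 0.20), Sox18 (-1.40 ± 0.21) and the heat shock gene Hspa1b (-2.32 ± 0.53). On the positive side were fatty acid synthase, Fasn (1.01 ± 0.20), Hk2 (1.85 ± 0.17), Hdc (1.47 ± 0.16), Cpt1b (1.45 ± 0.24), Pdpk1 (1.90 ± 0.32) and the serum amyloid gene Saa3 (0.93 ± 0.16). Over the 12 group values Pdpk1, Cpt1b, Hk2 and Hdc correlated with the germ cell list at r = 0.96, 0.82, 0.79 and 0.72. Saa3 and Fasn had 0.54 and 0.20. The list differs in HF4 as well, so a high r does not tell where a transcript comes from.

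Adjusted over the list alone, 7 adipocyte genes, 8 macrophage markers, 7 respiratory chain genes, 9 fatty acid oxidation genes, 6 prostanoid genes and 4 erythroid markers passed on the negative side in HF4 against HF4-REV. Over all genes it was 1, 3, 6, 0, 3 and 1. The count was 448 from the arrays holding both groups and 136 after quantile normalization. It was 1512 without HF3 with HF0, experiment 2 replicate 2, and 6458 or 4378 without HF4 with HF4-REV, replicate 1 or replicate 2.

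Averaged over the 3 generations, high fat against the normal diet after reversal put adipocyte genes on the negative side, 19 of 20 with a median of -0.42 (adjusted p = 1.22e-07, but adjusted p = 0.379 with an estimated correlation). Pck1 (-1.06 ± 0.17, adjusted p = 0.0419), Cidec (-1.02 ± 0.18) and Retn (-0.79 ± 0.09) passed the gene test, and 11 adipocyte genes passed adjusted over the list alone. Further genes past the threshold on that side were Mmp9, a matrix metalloproteinase (-1.51 ± 0.18, adjusted p = 0.0309), Cyp2e1 (-1.28 ± 0.15) and the carbonic anhydrase gene Car4 (-1.17 ± 0.20). Fech (-1.09 ± 0.16), Alas2 (-1.08 ± 0.13), Sox18 (-0.91 ± 0.13), Thrsp (-0.81 ± 0.15) and Npr3 (-0.64 ± 0.10) were negative too. On the positive side Crisp2 (4.24 ± 0.15, adjusted p = 0.00227) stood with Clec2m and Prm1. Also positive were Hk2 (1.10 ± 0.10), Il1rn (0.95 ± 0.11), Fabp3 (0.72 ± 0.13), Idi1, an enzyme of cholesterol synthesis (0.65 ± 0.09), and Hdc (0.65 ± 0.10).

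Fatty acid oxidation genes were negative for 19 of 20 in this average (median -0.26, adjusted p = 0.000608, but adjusted p = 0.379 with an estimated correlation). Erythroid markers had -0.29 (adjusted p = 0.0126, but adjusted p = 0.457 with an estimated correlation). Endothelial markers had -0.45 and male tract markers 0.67 (adjusted p = 0.00106 for both), T cell markers -0.40 (adjusted p = 0.00225), oxidative phosphorylation -0.15 (adjusted p = 0.0179) and extracellular matrix -0.17 (adjusted p = 0.0457). Each of those 5 had adjusted p = 0.695 with an estimated correlation. The male tract value holds STD of experiment 2 too, since HF3 and HF4 enter as averages over both experiments. In all, 722 genes passed, 622 positive and 100 negative. Of these calls 488 moved with the germ cell list (r above 0.8 in absolute value). Hk2, Fabp3 and Hdc, named above, correlated with that list at r = 0.79, 0.87 and 0.72. The list itself differs in HF3 and HF4, so this does not tell where a transcript comes from. The arrays holding both groups alone gave 0 by limma (4067 at an unadjusted p under 0.05). Leaving out 1 array moved the count to between 413, without HF3 with HF0, experiment 2 replicate 2, and 2123, without HF1 with HF1-REV, replicate 2.

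Whether the diet effect differed between generations was tested as a difference of differences. Between HF4 and HF1 the most positive values were those of Meig1 (4.68 ± 0.97) and Gtsf1, a germ cell gene of the piRNA pathway (4.38 ± 0.91). The most negative included Alox5ap, the activator of 5-lipoxygenase (-3.14 ± 0.97), Prrg1 (-3.14 ± 0.30), Lyz1 (-3.05 ± 0.98) and Fech (-3.02 ± 0.38). Here 0 genes passed limma's test (0 with the robust prior, 4210 at an unadjusted p under 0.05). Without HF1 with HF1-REV, replicate 1 or replicate 2, it was 1260 or 351, and without HF4 with HF4-REV, replicate 1 or replicate 2, 757 or 653.

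Between HF4 and HF0, where STD stands for the normal diet, the diet effects differed for 1223 genes, 1009 positive and 214 negative. Quantile normalization left 312, with 249 positive and 63 negative. Of the 1223 calls 768 moved with the germ cell list, which itself differs in HF4. Among the most positive were Prm1 at 8.35 ± 1.22 (adjusted p = 0.0226) and Crisp2 at 7.92 ± 0.31 (adjusted p = 0.0043). Among the negative genes were Fech at -2.50 ± 0.32 (adjusted p = 0.0179) and Alas2 at -2.35 ± 0.26, both of heme synthesis. Clec4a2 (-2.34 ± 0.33), C1qb (-2.13 ± 0.43), Ctss, which encodes cathepsin S (-1.94 ± 0.36), and Adgre1 (-1.54 ± 0.24) were negative too. Without HF4 with HF4-REV, replicate 1 or replicate 2, the count was 3448 or 2377.

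**Figure D3:**
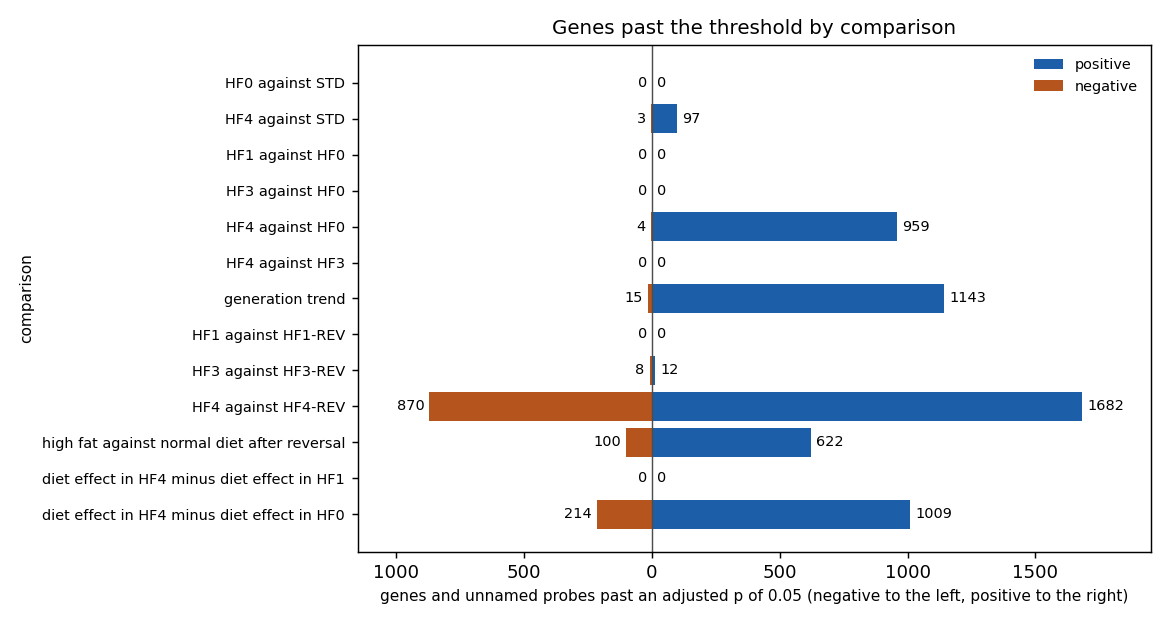
Number of genes and unnamed probes past an adjusted p of 0.05 in each comparison, positive values to the right and negative values to the left of 0. HF4 against HF4-REV has 1682 positive and 870 negative calls (927 and 204 under scale normalization), and 5 of the pairwise comparisons have 0.

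Of the 24 lists, 8 passed the camera threshold in none of the 11 comparisons: fat mass expansion genes, thermogenic genes, insulin signalling, imprinted genes, the circadian clock, and the markers of mast cells, mesothelium and skeletal muscle. Their lowest adjusted p was 0.0671, for mast cell markers in HF0 against STD.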

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

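The tests of epididymis RNA of 1 composition, hybridisation day, dye and other splits were chosen only after the result was seen. So were those of high fat feeding and of diet as whole causes. The tests on the Leydig and Sertoli cell list and on 11 epididymis genes were set before their values were looked at.

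The diet effect in HF4 (HF4 against HF4-REV) differed from that in HF0 (HF0 against STD) for 1223 genes by a test of the difference itself. Positive differences belonged to Prm1 (8.35), Tnp1 (8.13), Clec2m (8.10), Tnp2 (8.09), Meig1 (8.02), Crisp2 (7.92), Spz1 (7.86) and Mael (7.83), and to the epididymal Lcn5 (6.61). They also belonged to Pdpk1 (2.80), Cpt1b (1.66), Hk2 (1.56), Fabp3 (1.52) and Hdc (1.27). Negative differences belonged to Fech (-2.50), Alas2 (-2.35), Fabp6 (-2.35), Clec4a2 (-2.34), Prrg1 (-2.28), Cd300ld (-2.27), Calr4 (-2.17) and C1qb (-2.13). Further negative ones were Ccl8 (-1.96), Ctss (-1.94), Tyrobp (-1.83), Ltc4s (-1.77), Adgre1 (-1.54), Alox5 (-1.47), Hpgds (-1.13) and Uqcrfs1 (-1.11). STD stands on the normal diet side of 1 effect only, so its male tract transcripts enter this difference.

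The values of the 2 experiments were also set against each other, with the spread of pair averages within experiments as the error. Past the threshold were 1566 genes in HF0 against STD, 447 in HF4 against STD, 347 in HF3 against HF0, 32 in HF4 against HF0 and 303 in HF4 against HF3. The labels name no different extracts within an experiment, so that error holds array noise only, and separate extracts can pass with no change in the diet effect. The experiments also used different RNA reagents, so reagent and animals cannot be separated.

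Of 53 values tested over the 4 arrays of HF0 with STD in experiment 2, 3 had an array far from the others, where chance gives about 1 in 20. Ackr2 stood at 1.60 on replicate 1 (2.00 to 2.07 on the others), Ptgds at -3.27 on replicate 2 (-2.63 on each of the others) and Pla2g4a at 0.47 on replicate 1 (1.41 to 1.49 on the others).

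Male germ cell transcripts lay far apart between HF4 and HF0 in both experiments, with HF3 between them. Differing amounts of epididymis RNA of 1 composition are argued against: in experiment 2 the epididymis list lay at -3.83 in HF4 minus STD, with 22 of 23 members on that side, and the germ cell list at 1.61, with 29 of 31 on the other. RNA of whole testis stays open, since 19 Leydig and Sertoli cell genes had a median of 0.22 and 0.14 in HF4 against HF0, at percentiles 99.98 and 99.61 among 10000 random lists, though these shifts are small beside 2.66 and 3.31. In limma's test 0 of the 19 passed there (5 at an unadjusted p under 0.05, all positive), which cannot decide, since shifts this small are mostly beyond the design. That 25 of the 31 germ cell genes passed does not bear on it, as their shifts are far larger. STD of experiment 2 had 0.26, beyond HF4, with a lower germ cell median, which would go against whole testis RNA. That extract also stands apart in epididymis transcripts, so its value does not decide. In experiment 1 STD had -0.04 and HF4 0.22, the order that whole testis RNA would give. Whether testis tissue in the dissected fat may stand behind part of the values is left open. High fat feeding over generations as the whole cause stays open as well. HF3 and HF4 (2.01 and 3.31 in experiment 2) go with it against HF3-REV and HF4-REV (0.13 and -0.01), but STD at 1.70 goes against it. The 5 sperm genes of the list fixed beforehand go against it in experiment 2, at 4.77 in STD, 3.72 in HF3 and 4.95 in HF4. In experiment 1 they go with it, at 0.89, 2.21 and 3.54. The values of STD in experiment 2 do not settle it, since that extract also stands apart in epididymis transcripts, which may come with sperm if Cy5 was the numerator.

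Epididymis transcripts set the STD extract of experiment 2 apart from the other 7 groups. Hybridisation day as the cause is argued against, since HF0 against STD had a list median of -4.14 on 1 day and -4.80 on the other. Diet as the whole cause is argued against by the experiments, whose STD medians differed by 3.23. A list of 11 epididymis genes that had not been looked at had a median of 3.50 in that extract (random lists -0.20 to 0.24). This is what epididymis RNA in the extract would give if Cy5 was the numerator. The lists of 11 and 23 epididymis genes have the same lowest value there (-0.02), so they are not taken as separate sets. The shift may thus be a matter of dissection, and values against STD in experiment 2 carry it. Comparisons of HF0, HF3 or HF4 with HF1 or a reversal group carry part of it. There STD enters through the mean of the groups that both experiments share.

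All signs depend on which dye was the numerator. If it was Cy5, the STD extract of experiment 2 holds more epididymis RNA than all others, at a distance of 3.83 from the nearest of the 7 groups, whose range is 0.89. If it was Cy3, 7 groups would share that RNA and STD alone lack it, which speaks for Cy5 but does not settle it, and no sign was read from it. On the Cy3 reading the lipogenesis list would have a mean of 0.48 in HF0 against STD of experiment 2, and 0.16 in experiment 1, which does not exclude that reading, because the fat mass expansion list would turn with it, to 0.12 and 0.09.

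For high fat against normal diet after reversal, the 6 groups of experiment 2 can be split in 10 ways, and 3 of the splits gave as many genes, the real one included. The real split gave 722 and the highest other 1706, for HF1, HF1-REV and HF4-REV against the rest. The splits are too few for a share under 0.05.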

How the results depend on the processing

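The alternatives without the features that move with the germ cell list and without the STD extract of experiment 2 were chosen only after the results had been seen. Of the 13 counts of genes, no centring and the robust prior left 13 within 1.5 times. Turned signs and only features measured on all 34 arrays change no count by construction. Of 164 calls of named genes 163 stayed past the threshold without centring, 125 with scale and 89 with quantile normalization, 126 with each probe on its own, 139 without the last hybridisation day, 135 with the spread of arrays within experiments, and 160 each with all arrays as replicates and experiment 2 alone. Experiment 1 alone kept 0 of 25 and only arrays holding both groups 26 of 142. No call of a named gene turned its sign, while of named values without a call 1 of 263 did under scale normalization, 9 of 131 in experiment 1 alone, 1 of 263 in experiment 2 alone, 8 of 247 on arrays holding both groups and 2 of 263 without the last day. Of all 6738 calls, signs turned only where an array of a reversal pair was left out (each probe on its own was not examined so). In HF4 against HF4-REV it was 95 and 84 of 2552 without its replicates 1 and 2, in the diet effect of HF4 minus HF0 32 and 17 of 1223, in HF3 against HF3-REV 2 and 2 of 20, and in the mean over reversals 4 of 722 at most. The cause was not tested unless named below.

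Of 264 list tests, 73 passed with camera, 0 with camera at an estimated correlation (lowest adjusted p 0.282) and 0 with the directional test of fry (lowest 0.0506), while 45 passed with fry without regard to direction; experiment 1 alone gave 26 of 120.

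Scale normalization gave 345 in HF4 against STD, 141 in HF3 against HF0, 248 in HF3 against HF3-REV (188 positive, 60 negative) and 1131 in HF4 against HF4-REV (927 positive, 204 negative). Quantile normalization gave 0 in HF4 against STD, 210 in HF3 against HF3-REV (87 positive, 123 negative), 136 in HF4 against HF4-REV, 349 for the mean over reversals and 312 for the diet effect of HF4 minus HF0. Each probe on its own gave 46 in HF4 against STD and 0 in HF3 against HF3-REV, and leaving out the last hybridisation day 195 and 0.

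In the order HF0 and HF4 against STD, HF1, HF3 and HF4 against HF0, HF4 against HF3, slope, HF1, HF3 and HF4 against their reversal groups, mean over reversals, and diet effect of HF4 minus HF1 and minus HF0, the spread of arrays within experiments gave 2344, 3004, 2232, 2302, 2911, 1367, 2661, 64, 198, 4888, 2490, 1365 and 5493. All 34 arrays as replicates gave 3390, 4017, 2667, 3270, 3413, 2704, 3181, 67, 854, 5346, 3335, 2339 and 5743. Experiment 2 alone gave 5848, 3469, 3627, 4906, 3075, 4544, 3795, 149, 1403, 6474, 4469, 3550 and 6789. By construction these take the spread within experiments rather than that between them, so they do not say how well the extracts repeat. The first, and experiment 2 alone, use dye-swap averages, so their error is how well the pairings fit together. Each reversal group hangs on 1 such average and adds nothing to that error. Those counts thus do not say whether the arrays of a reversal pair repeat. Only all 34 arrays as replicates also takes the spread between the arrays of a dye swap. Experiment 1 alone gave 0 in HF4 against STD and in HF4 against HF0.

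Only arrays holding both groups gave 3 in HF0 against STD, 0 in HF4 against STD, 2 in HF1 against HF0, 0 in HF4 against HF0, 448 in HF4 against HF4-REV, 0 for the mean over reversals, and 3 and 360 for the diet effect of HF4 minus HF1 and minus HF0; the slope could not be run so, and fewer arrays enter. Without the features that move with the germ cell list, limma gave 0 in HF4 against STD and HF4 against HF0, for the slope, the mean over reversals and the diet effect of HF4 minus HF0, 41 in HF3 against HF3-REV and 1044 in HF4 against HF4-REV. Since that list is itself far from the rest in HF4, the filter takes out genes for differing there, so these counts follow from its construction and do not show what the genes are. Without the STD extract of experiment 2 it gave 898 in HF4 against STD, 584 in HF3 against HF0, 252 in HF4 against HF3, 8, 886 and 4884 in HF1, HF3 and HF4 against their reversal groups, 2163 for their mean and 1254 for the diet effect of HF4 minus HF1. All alternative counts of 0, 282 of them, had between 327 and 4536 genes at an unadjusted p under 0.05.

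Leaving out each array in turn gave 0 to 0 in HF0 against STD, HF1 against HF0 and HF4 against HF3, 879 to 1016 in HF4 against HF0 and 1068 to 1214 for the slope. HF3 against HF0 ranged from 0 to 1, with 1 without HF0 with STD (experiment 1 replicate 1, experiment 2 replicate 2), HF4 with HF0 (experiment 2 replicate 1) or HF4 with STD (replicate 2). HF4 against STD ranged from 45 to 147, with 45 and 63 without HF3 with HF0 of experiment 2 (replicates 2 and 1), 53 without HF3 with STD (replicate 1), 56 without HF0 with STD of experiment 2 (replicate 2) and 61 without HF3 with HF1 (replicate 2). HF1 against HF1-REV ranged from 0 to 281, with 166 and 281 without its own arrays (replicates 1 and 2). HF3 against HF3-REV ranged from 0 to 2300 and moved for 23 of the 34 arrays, to 1702 and 2300 without its own (replicates 1 and 2). HF4 against HF4-REV ranged from 1512, without HF3 with HF0 (experiment 2 replicate 2), to 6458, with 6458 and 4378 without its own. The mean over reversals ranged from 413 to 2123: 413 without HF3 with HF0 and 459 without HF0 with STD (experiment 2 replicates 2 and 1), 2123 without HF1 with HF1-REV (replicate 2), 1573 and 1238 without HF3 with HF3-REV, 1639 and 1328 without HF4 with HF4-REV. The diet effect of HF4 minus HF1 ranged from 0 to 1260, with 1260 and 351 without HF1 with HF1-REV, 757 and 653 without HF4 with HF4-REV, and 1 without HF4 with HF3 (experiment 1 replicate 1 or experiment 2 replicate 2). That of HF4 minus HF0 ranged from 869 to 3448, with 3448 and 2377 without HF4 with HF4-REV. The remaining array of a pair is assumed to vary like the others. Its dye effect no longer cancels, and the fit has no dye term. The higher counts and the sign turns without an array of a reversal pair thus hold dye effects and cannot be read as diet effects. No paired analysis was possible because the labels pair no animals across groups. Signal over background was not used here, since the table holds no intensities.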

Other observations

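These values were picked only after the results had been seen and were not tested. In experiment 2 the adipocyte list had a median against HF0 of 0.62 in STD, 0.48 in HF1, 0.07 in HF3 and -0.06 in HF4, and of 0.92, 0.38 and 0.63 in HF1-REV, HF3-REV and HF4-REV. Every group on the normal diet thus lay on the same side of HF0, with HF1 among them. In experiment 1 it was 0.49 in STD, -0.08 in HF3 and -0.02 in HF4. The erythroid markers had medians of 1.16 in HF1, 1.15 in HF1-REV and 0.85 in HF4-REV against HF0. In the other groups of experiment 2 they had 0.23 in HF3-REV, 0.08 in HF3, 0.06 in STD and -0.18 in HF4.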
